A study of Mus musculus with 24 samples.

How the data were processed

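The RNA tables were deposited as raw counts of fragments per gene, and per the file headers they were made with featureCounts 2.0.1 on GENCODE M29 gene models, without strand information. Per the labels, reads were trimmed with Trimmomatic 0.39 and aligned with STAR 2.7.10a, and both GRCm39 and GRCm38 are listed as genome builds. The coordinates printed here are those of the deposited tables, whose headers name a GRCm39 annotation. Of 55414 genes in the tables, 52081 were given symbols from a reference table that was used for names only. The TCR and BCR tables were deposited with a read count and a fraction for each assembled CDR3, the fraction being computed by the authors over a total for each TCR chain, for IGH, or for both light chains together. The TCR totals exceed the listed reads, as the deposited fractions sum to between 0.838 and 0.875 for TRA and between 0.937 and 0.954 for TRB. The program that made these tables is not given in the sources used here. The deposited fractions were not used, and shares were computed from the counts. Per the labels, all samples are spleen of BALB/c mice and RNA was extracted with the Takara MiniBEST kit, and the Takara SMARTer mouse TCR a/b kit is named for library construction.

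Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR's robust quasi-likelihood test (titled CT-26 minus titled control), and p was adjusted by the method of Benjamini and Hochberg at 0.05. Replicate numbers were not treated as pairs, because no label says that they mark a shared day or litter. Correlations of log2 CPM between libraries of equal number, each gene's mean in its set removed, lay between -0.0914 and 0.0764. CPM use TMM-scaled totals, and each value after ± is an SD over 4 libraries unless named SE. Counts were made without strand, so genes that overlap on opposite strands, and families of near-identical copies such as the Ifi200, Gimap, Ms4a4, Ighg and haemoglobin genes, have uncertain levels. The 35 marker lists, the tests, and the alternatives in the planned table were fixed before the data were examined. Lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, adjusted over 18 lists, and with fry as an alternative. Genes are named by a fixed rule: the 12 largest changes in each direction with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between sets, and in each list up to 4 genes of smallest p. Further members of a list that are named were chosen after their values were seen. A few genes that meet the rule are not reported here.

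Receptor entries were kept when in frame, free of stop codons and with V and J of the same chain, and were joined into clonotypes by V, J and CDR3 nucleotide sequence. Clonotype number and clonality (1 minus normalised Shannon entropy) were means of 20 random draws at the read total of the smallest library of that chain. Groups were compared by exact permutation over all 70 assignments, two-sided, adjusted over 10 tests for number and clonality, over 8 isotypes, over 2 invariant rearrangements and over 5 chains for CDR3 length. Overlap used CDR3 amino acid sequences, with permutation over the 35 splits of 8 libraries into sets of 4. With 1 library left out, the group comparisons used 35 assignments of 3 against 4 libraries. A call could then be lost although the sets did not overlap. V segments with a mean of at least 10 clonotypes were tested with edgeR's quasi-likelihood test on clonotype numbers without TMM, adjusted within each chain, and the 4 of smallest p per chain are named. Limits for counts of 0 use 3 reads over the total.

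With changes built into simulated counts, the RNA procedure found 51.8% of 2-fold and 97.6% of 4-fold changes, with 3 false among 130 calls. The V segment procedure found between 88.0% and 100% of 2-fold changes. It made 4 false calls in IGHV, where 25 of 125 segments were changed, and 0 in the other chains. The RNA changes were built into 200 genes, fewer than were called in the data. The V segment simulation used 1 set spread for all segments and about as many rises as falls. These rates need not hold for the data. No pair of libraries within a set was a copy of another by counting noise, the lowest chi-square per degree of freedom being 4.28 for RNA and 3.30 for receptor chains. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.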

Results

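The spleens of BALB/c mice were profiled by RNA-seq, by sequencing of T cell receptor (TCR) transcripts and by sequencing of B cell receptor (BCR) transcripts. CT-26 is a mouse colon carcinoma cell line derived from this strain. Each of 8 titles, 4 titled control and 4 titled CT-26, had 1 library of each kind, which made 24 libraries. The treatment field contradicts the titles: the libraries titled control carry the treatment of injected CT-26 cells, and those titled CT-26 carry the treatment of healthy controls. Both fields split the libraries into the same sets of 4, so the sets are named by their titles below, no result is read as tumour against healthy, and every fold change is titled CT-26 minus titled control. The RNA libraries held between 735298 and 1970950 counts and between 11890 and 13946 genes with a count. The TCR libraries held between 159604 and 236935 reads in the titled control set and between 34295 and 79721 in the titled CT-26 set. The BCR libraries held between 863374 and 909745 reads and between 731857 and 840210 reads, respectively.

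The first comparison followed the aim of the series, a contrast of the spleen transcriptomes of the CT-26 model and of normal mice. Most measured markers of B cells, T cells, natural killer cells and red pulp macrophages were lower in the titled CT-26 spleens. Most of those of red blood cell precursors, immature neutrophils and dividing cells were higher. This is read from marker genes tested singly and from 12 lists called by camera at its preset correlation, of which 0 were called at a correlation estimated from the data (5 at an unadjusted p under 0.05; fry called 14). The difference ran through much of the transcriptome. Of 6408 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1359 were higher and 1381 were lower in the titled CT-26 libraries. Among these 2740 genes, 1961 differed by at least 2-fold and 581 by at least 4-fold. The libraries of both sets did not overlap for 2470 genes, 38.6% of those tested, where chance gives 2.86%. With the sequencing lane as a factor in the model, 2006 genes passed. Each edgeR p takes the 4 RNA libraries of a set as separate samples, which the labels do not state. Scaling by library totals without TMM moved all fold changes up by a median of 0.37 on the log2 scale, and 1936 genes were then higher and 725 lower. No gene called under both scalings changed direction. Pearson's r of log2 CPM, taken across genes, lay between 0.902 and 0.935 within the sets and between 0.668 and 0.770 across them.

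Among genes that met the naming rule, which leaves out low levels, the largest increase was that of Per1 (ENSMUSG00000020893, chromosome 11, 68986043 to 69000786, GRCm39), a repressor of the circadian clock that also responds to glucocorticoids. Its level rose from 1.07 ± 2.15 CPM to 73.4 ± 13.3 CPM (SD, n = 4 per set), a log2 fold change of 6.30 ± 0.52 (SE) with an edgeR adjusted p of 4.19e-10. Its titled control level rests on 4 counts in titled control 3, and against the 0 counts of the other 3 libraries the log2 fold change is at least 6.64. Genes of the granules that developing neutrophils build rose steeply. Mpo, which encodes myeloperoxidase, went from 1.85 ± 1.65 to 66.2 ± 26.3 CPM, and the serine proteases Prtn3 and Elane had log2 fold changes of 4.71 and 4.16. The decoy interleukin 1 receptor Il1r2, carried by mature neutrophils, changed by 4.55, and the basophil protease Prss34 by 4.37. Ighe, the constant region of IgE, changed by 4.87, from 0.868 ± 1.14 to 32.8 ± 17.2 CPM. The other members of the 12 largest increases were the endothelial lipase Lipg, the MAP kinase phosphatase Dusp8, the matrix glycoprotein Thbs1, the cell cycle transcription factor Mybl2 and the F-box gene Lrrc29, with log2 fold changes between 4.17 and 5.57. Low titled control levels made some of these depend on 1 library: Mpo and Il1r2 had 5.91 and 5.20 without titled control 1, Lrrc29 had 4.84 without titled control 2, and Ighe, Thbs1 and Prss34 had 6.26, 5.52 and 4.99 without titled control 4.

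The largest decrease among such genes was that of Ms4a4c (ENSMUSG00000024675, chromosome 19, 11382134 to 11404610), a surface protein of blood cells. It fell from 44.8 ± 8.45 to 0.284 ± 0.568 CPM, a log2 fold change of -7.07 ± 0.57 (SE) with an edgeR adjusted p of 9.79e-11. Its titled CT-26 counts lay in titled CT-26 4 alone, and against the 0 counts of the other 3 libraries it fell by a log2 fold change of at least 5.78. Cr2, the complement receptor by which B cells and follicular dendritic cells bind opsonised antigen, fell from 439 ± 131 to 26.5 ± 5.73 CPM. Genes of killer lymphocytes fell as well: the granzyme Gzma from 136 ± 46.5 to 7.64 ± 3.56 CPM, and the natural killer receptor Ncr1 from 49.9 ± 20.4 to 1.55 ± 2.54 CPM, a log2 fold change of -4.89, or -6.92 without titled CT-26 1. Clec2d, a ligand of natural killer receptors, and the lymphocyte GTPase Gimap7 had log2 fold changes of -5.28 and -4.33. Ifi214 and Ifi209, interferon-inducible members of the p200 family, changed by -4.75 and -4.52, although counts of this family may be shared between near-identical copies. The prostaglandin-degrading enzyme Hpgd, the DNA-binding protein Nabp1, the kynurenine enzyme Kmo and the chaperone Hsph1 completed the 12 largest decreases, between -5.17 and -3.96, with Nabp1 at -5.54 without titled CT-26 1. Hsph1 varied widely among the titled control libraries, 71.4 ± 74.7 CPM, had a log2 fold change of -2.87 without titled control 4, and lost its call when titled CT-26 replicate 1, 2 or 3 was left out.

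**Figure D1:**
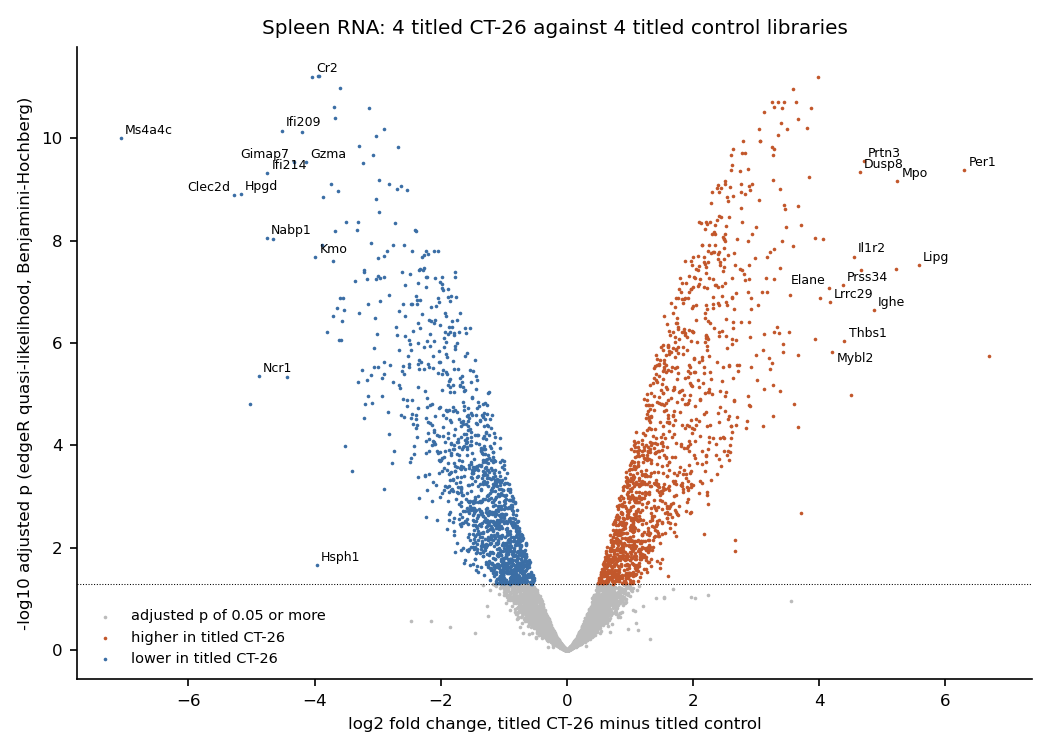
Log2 fold change (horizontal axis, titled CT-26 minus titled control) against -log10 of the edgeR adjusted p (vertical axis) for the 6408 genes tested in 4 libraries per set. Points are genes, coloured where the adjusted p was under 0.05 (dotted line), and the 12 largest changes in each direction that met the naming rule are labelled, from Ms4a4c at -7.07 to Per1 at 6.30.

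Marker lists of lymphocytes pointed one way, by camera at its preset correlation. No list call here or in the next 2 paragraphs held with camera at a correlation estimated from the data. All 12 B cell markers were measured and 11 were lower (11 when adjusted over the list alone), with a median log2 fold change of -1.97 and a camera adjusted p of 5.69e-08 (0.174 with an estimated correlation). The B cell surface protein Ms4a1 (CD20) changed by -3.93 ± 0.25 (SE), and Fcer2a (CD23), a marker of follicular B cells, fell from 240 ± 61.3 to 18.4 ± 12.5 CPM. The B cell scaffold gene Bank1 changed by -3.13. Of 15 T cell genes, 14 were lower (15 when adjusted over the list alone), with a median of -1.74 and a camera adjusted p of 1.02e-07 (0.174 with an estimated correlation). The CD8 coreceptor genes Cd8a and Cd8b1 changed by -3.60 and -3.00, Cd3g of the receptor complex by -2.56, and the receptor constant gene Trbc1 by -2.58. Of 8 genes of naive T cells, 6 were lower (7 when adjusted over the list alone), with a median of -1.34. The survival receptor Il7r, the egress receptor S1pr1 and the quiescence factor Klf2 changed by -1.78, -1.85 and -1.31. All 5 cytotoxic and NK genes were lower (5 when adjusted over the list alone), with a median of -3.30, among them the NK receptor Klrd1 at -3.30 and the chemokine Ccl5 at -1.57.

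Macrophages of the red pulp recycle iron from old red cells. Of 11 of their markers, 7 were lower (8 when adjusted over the list alone), with a median log2 fold change of -1.70 and a camera adjusted p of 0.000373 (0.174 with an estimated correlation). The transcription factor Spic that specifies these cells changed by -3.31, the iron exporter Slc40a1 fell from 232 ± 26.2 to 36.1 ± 5.19 CPM, and the haem-degrading enzyme Hmox1 fell from 499 ± 36.4 to 116 ± 32.7 CPM. The receptor Axl, which clears dying cells, changed by -1.70. The other 4 markers did not pass. Among them, Vcam1 had 480, 724, 344 and 666 counts in the titled control libraries and 732, 703, 602 and 588 in the titled CT-26 libraries. Of 5 genes of plasmacytoid dendritic cells, 4 were lower (4 when adjusted over the list alone), with a median of -1.77. The homing receptor Ccr9 changed by -3.71, Ly6d by -3.08 (-4.20 without titled CT-26 1), Irf8 by -1.15, and Siglech by -1.77, a call that ended when titled CT-26 replicate 1 was left out. Of 9 genes of MHC class II presentation, 8 were lower (8 when adjusted over the list alone), with a median of -1.15. The modulator H2-Ob, found mostly in B cells, fell from 219 ± 81.7 to 22.3 ± 2.80 CPM, while the class II chain H2-Ab1 changed by -1.26, and the peptide loaders H2-DMb2 and H2-DMb1 by -1.38 and -1.47. Of the 13 mitochondrially encoded genes, 12 were lower (12 when adjusted over the list alone), with a median of -1.19, and the least adjusted p belonged to mt-Atp6, mt-Nd4l, mt-Co2 and mt-Co3, at -1.66, -2.48, -1.49 and -1.49. All genes with a mitochondrial symbol, not the 13 of this list alone, took 54.8% ± 9.15 of the titled control counts. In the titled CT-26 libraries they took 37.5% ± 3.91 (SD, n = 4 per set).

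Red cell precursors, immature neutrophils and dividing cells pointed the other way. Of 19 erythroid genes, 16 were higher (16 when adjusted over the list alone), with a median log2 fold change of 1.72 and a camera adjusted p of 1.16e-07 (0.189 with an estimated correlation). The anion exchanger Slc4a1 of the red cell membrane rose from 138 ± 22.8 to 1492 ± 381 CPM, and the membrane proteins Rhag and Ermap changed by 2.53 and 2.76. The most abundant haemoglobin transcripts Hbb-bs, Hbb-bt and Hba-a2 did not pass, at 0.07, 0.00 and 0.45. All 9 genes of neutrophil precursor granules were higher (9 when adjusted over the list alone), with a median of 3.38 and a camera adjusted p of 1.02e-07 (0.175 with an estimated correlation). The granule protein Ngp rose from 236 ± 78.3 to 2452 ± 853 CPM, and the chitinase-like Chil3 changed by 4.05. Of 8 mature neutrophil genes, 5 were higher (5 when adjusted over the list alone), with a median of 1.71. The alarmin S100a9 rose from 439 ± 204 to 2829 ± 923 CPM, its partner S100a8 changed by 2.11, and the collagenase Mmp8 by 2.19. All 19 cell cycle genes were higher (19 when adjusted over the list alone), with a median of 2.32 and a camera adjusted p of 5.49e-12 (0.174 with an estimated correlation). The cell division genes Aurkb, Birc5, Ccnb2 and Ccna2 changed by 3.86, 3.26, 3.06 and 2.60.

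The preset camera test thus called 12 of the 18 lists with at least 5 measured members. With a correlation estimated from the data, camera called 0 lists, with 5 at an unadjusted p under 0.05, and fry, which asks only whether a list moves one way, called 14. The lists that did not pass were mixed. Of 11 immunoglobulin constant genes, 3 were higher and 5 lower (3 and 5 when adjusted over the list alone), so that their mean log2 fold change of 0.03 and their median of -0.48 differed in sign. Of 7 monocyte genes, 4 were lower and 1 higher (4 and 1 when adjusted over the list alone), with the receptors Csf1r and Clec4a1 at -1.14 and -2.26, the lysozyme Lyz2 at -0.77 and Plac8 at -1.65. Of 9 immediate early and heat shock genes, 5 were higher and 1 lower (5 and 1 when adjusted over the list alone), with Dusp1, Ier3, Fos and Jund at 2.68, 2.58, 1.87 and 1.65. MHC class I presentation had 4 of 8 genes lower (4 when adjusted over the list alone), with Psmb9 at -1.62 (-2.25 without titled CT-26 1), Nlrc5 at -0.88, B2m at -0.79 and Psmb8 at -0.70, and the last 3 lost their calls without TMM. Nlrc5 also lost its call without titled control 2, 3 or 4 or titled CT-26 2 or 3, and Psmb8 without titled control 3 or titled CT-26 2 or 3. The unfolded protein response had 1 higher and 2 lower of 8 (1 and 0 when adjusted over the list alone), with the degradation factor Herpud1 at 1.14, the chaperone Dnajb9 at -0.64, the chaperone Pdia4 lower as well, and Hspa5 not passing. The Dnajb9 call was lost without titled control 3 or 4 or any of titled CT-26 1 to 4, and that of Pdia4 without titled control 1 or 2 or titled CT-26 1, 2 or 4. Glycolysis had 1 higher of 8 (1 when adjusted over the list alone), the isomerase Gpi1 at 0.82, while Gapdh, Ldha and Pgk1 did not pass.

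**Figure D2:**
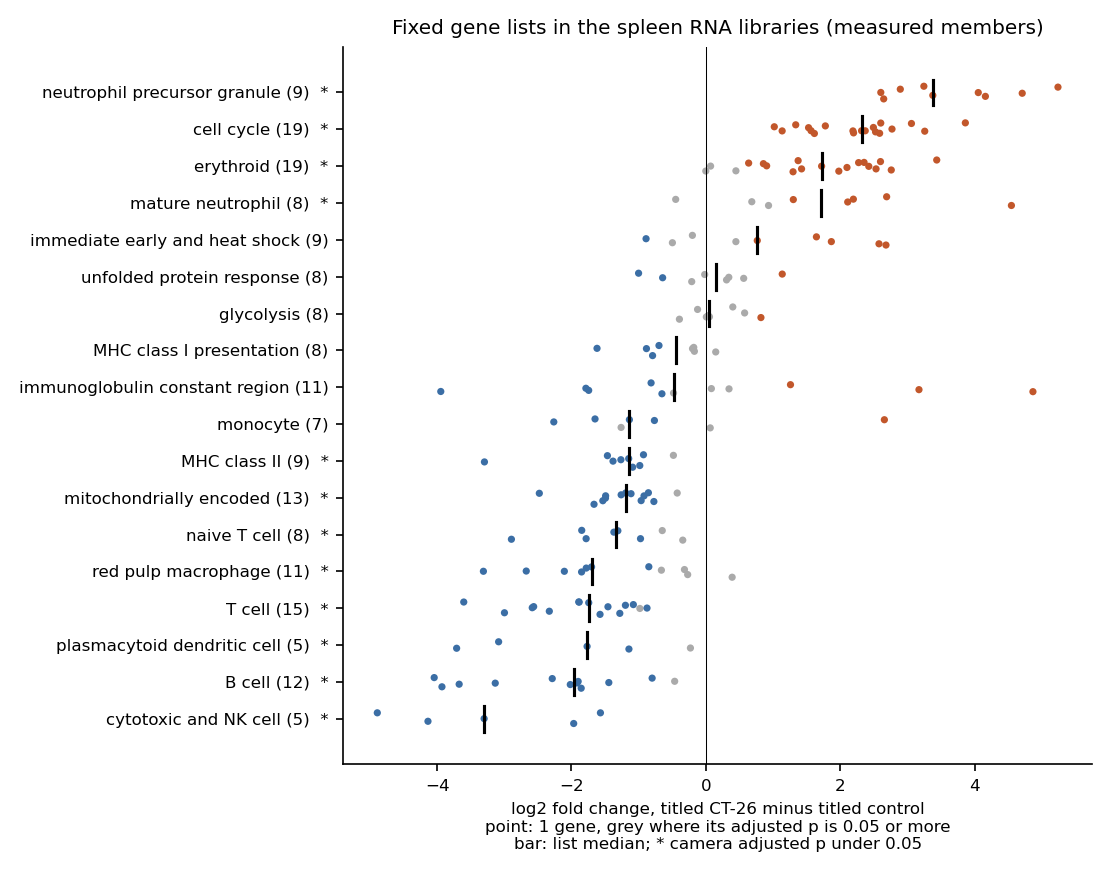
Log2 fold change (horizontal axis, titled CT-26 minus titled control, 4 libraries per set) of the measured members of the 18 tested lists, with their number in brackets. Points are genes, grey where the edgeR adjusted p was 0.05 or more, bars are medians and asterisks mark the 12 lists called by camera, whose medians run from -3.30 for cytotoxic and NK genes to 3.38 for neutrophil precursor granules.

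A further 17 lists had fewer than 5 measured members and were not tested as lists. Among interferon-stimulated genes, the antiviral enzyme Rsad2 rose from 151 ± 51.0 to 1021 ± 196 CPM, whereas Ifi44 and the regulator Irf7 fell, with log2 fold changes of -3.18 and -1.24. The plasma cell genes Jchain, Irf4 and Xbp1 changed by -0.54, -0.62 and -0.08, of which Jchain alone passed, with a call that ended without TMM and without titled control 1 or 3 or titled CT-26 2, 3 or 4. The regulatory T cell factor Foxp3 changed by -1.44, a call that also ended without TMM and without titled control 3, and the ectonucleotidase Entpd1 of the inhibitory receptor list by -1.19. Cd84 of the myeloid suppressor list changed by -2.02 and Wfdc17 of the same list by 0.00, the dendritic integrin Itgax by -1.51, and the cytokine Tnf by -1.74, while Il1a did not pass. Kit, the stem cell factor receptor of the progenitor and mast cell lists, changed by 1.06, a call lost without titled control 2 or titled CT-26 2 or 4, and Myb and Cpa3 did not pass. Pf4, Itgb3 and Ppbp of the platelet list, Col1a1, Cxcl13 and Col1a2 of the stroma list, Neil1 of the germinal centre list and Xist of the sex-linked list did not pass. The endothelial gene Pecam1 changed by -0.91, with a call that ended without TMM, and Stab2 and Plvap did not pass. Acsl1, a fatty acid enzyme on the adipocyte list, changed by 2.82. The exocrine pancreas list, a check for tissue carried over at dissection, had Cela1 at -2.06 (-1.20 without titled control 4), and Cpa1 and Ctrb1 did not pass. No gene of the epithelial list was measured.

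The second comparison asked whether the T cell repertoire differed between the sets. The titled CT-26 libraries gave fewer distinct T cell clonotypes at equal read depth, and their reads were less evenly spread over clonotypes. Equal depth here means equal reads, not equal input molecules. A smaller input of T cell RNA would lower these numbers too and could change the evenness. The numbers are not counts of clones in the spleen. A clonotype was a productive receptor chain with 1 V segment, 1 J segment and 1 CDR3 nucleotide sequence, the CDR3 being the hypervariable loop that meets antigen. At 16656 reads, the alpha chain (TRA) gave 10582 ± 819 clonotypes in the titled control libraries and 4499 ± 733 in the titled CT-26 libraries (SD, n = 4 per set; exact two-sided permutation p = 0.0286, adjusted p = 0.0317). At 14939 reads, the beta chain (TRB) gave 10212 ± 829 and 3620 ± 769 clonotypes, a 2.82-fold difference (exact permutation p = 0.0286, adjusted p = 0.0317). Clonality, which is 0 for an even repertoire and 1 for a single clone, was 0.0199 ± 0.00318 and 0.0954 ± 0.0249 for TRA and 0.0159 ± 0.00331 and 0.105 ± 0.0224 for TRB, each with the same exact permutation p. Without clonotypes of 1 read the gap was smaller, although the sets still did not overlap. TRA clonality was then 0.0187 to 0.0235 in the titled control set and 0.0388 to 0.0626 in the titled CT-26 set. For TRB it was 0.0129 to 0.0201 and 0.0450 to 0.0683. The p of 0.0286 is the smallest that 70 assignments of 4 against 4 libraries can give. Leaving out titled control 1, 2, 3 or 4 raised the permutation adjusted p of TRA clonality to 0.0635, although the sets still did not overlap. The largest TRB clonotype of each library took between 0.0655% and 0.171% of reads in the titled control set and between 0.294% and 0.756% in the titled CT-26 set. The highest of these was TRBV13-2 with TRBJ1-4 in titled CT-26 4, at 113 of 14939 reads (0.756%, 95% Wilson interval 0.630% to 0.909%). The reads carried no molecular identifiers in the tables, so this interval, and the limits given for counts of 0, cover counting error only.

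The B cell repertoire differed most in the heavy chain (IGH). Each p and SD of the BCR results takes the titled control libraries as separate samples. That is in doubt, because these libraries share most of their abundant IGH clones (below). At 162551 reads there were 58470 ± 2175 IGH clonotypes in the titled control libraries and 40960 ± 1322 in the titled CT-26 libraries (SD, n = 4 per set; exact permutation p = 0.0286, adjusted p = 0.0317), with clonalities of 0.153 ± 0.0137 and 0.210 ± 0.00536. The kappa chain (IGK) gave 36387 ± 621 and 36231 ± 396 clonotypes at 292851 reads, a difference within the spread (exact permutation p = 0.800), while its clonality rose from 0.304 ± 0.00414 to 0.320 ± 0.00145. Both depended on clonotypes of 1 read: without these the IGK number differed by -3526 (permutation adjusted p = 0.0408), and the clonality call was lost (permutation adjusted p = 0.159). The lambda chain (IGL) moved the other way, from 6151 ± 131 to 7022 ± 244 clonotypes at 111359 reads, and its clonality fell from 0.566 ± 0.00152 to 0.555 ± 0.00462; these 3 differences had an exact permutation p of 0.0286. Without clonotypes of 1 read the IGL number differed by -20.8, the opposite sign (permutation adjusted p = 0.886). The IGL clonality call was then lost too (permutation adjusted p = 0.0714). With these clonotypes kept, it was lost without titled control 1, 2, 3 or 4 (permutation adjusted p = 0.0635), although the sets still did not overlap. The largest lambda clonotype was IGLV1 with IGLJ1 in all titled control libraries, at 20.3% to 21.0% of reads, and IGLV2 with IGLJ2 in all titled CT-26 libraries, at 19.2% to 23.5%. Both CDR3 sequences were abundant in every library. Matched by CDR3 sequence, titled control 1 had 38319 reads of the first and 31659 of the second. Titled CT-26 1 had 25255 and 33579. Among heavy chains, the largest clonotype took between 1.56% and 2.54% of reads in the titled control set and between 2.18% and 4.52% in the titled CT-26 set.

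**Figure D3:**
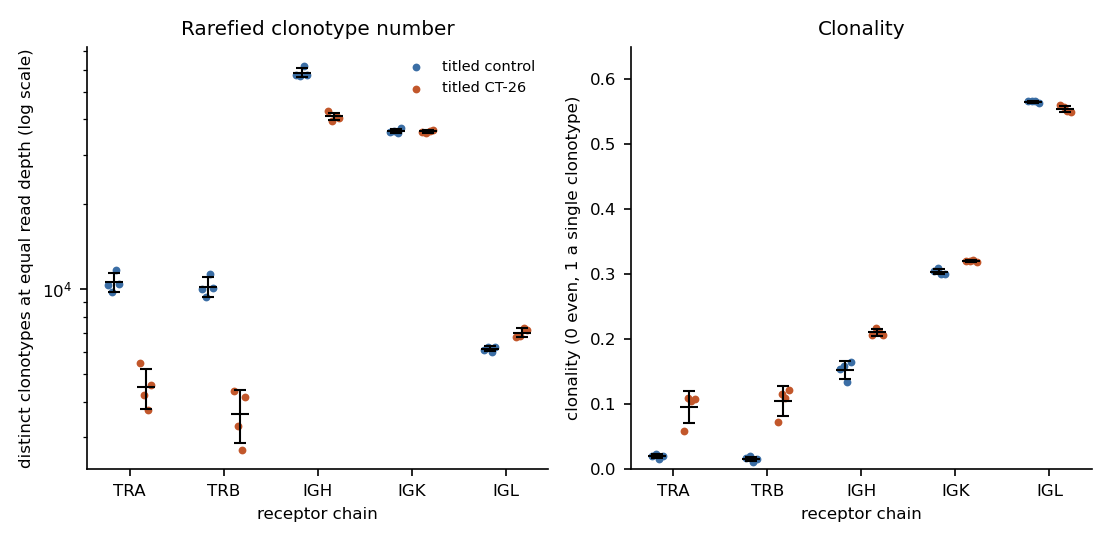
Distinct clonotypes at equal read depth (left, log axis) and clonality (right, 0 to 1) for each receptor chain. Points are the 4 libraries of a set, and bars are the mean and SD; TRA, TRB and IGH clonotype numbers of all titled CT-26 libraries lie under those of all titled control libraries, as with 10582 ± 819 against 4499 ± 733 for TRA.

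Heavy-chain isotypes, the classes into which B cells switch after activation, shifted away from IgD and IgM. IgD, which naive B cells carry beside IgM, took 5.44% ± 0.582 of IGH reads in the titled control libraries and 0.294% ± 0.0391 in the titled CT-26 libraries (SD, n = 4 per set), 18.5-fold less. IgM fell from 74.2% ± 0.658 to 61.7% ± 5.58. IgG1 rose from 0.843% ± 0.212 to 7.03% ± 1.65, 8.34-fold, IgG2a/c from 2.80% ± 0.580 to 9.27% ± 2.23, IgG3 from 1.98% ± 0.322 to 5.85% ± 1.86, and IgG2b from 1.02% ± 0.126 to 1.68% ± 0.332. IgE, the class of allergy and worm defence, rose from 0.0167% ± 0.0131 to 0.536% ± 0.281, 32.0-fold. These 7 isotypes had an exact permutation p of 0.0286 and an adjusted p of 0.0327. For each, all 4 libraries of one set lay above all 4 of the other. These p take the 4 titled control libraries as separate samples, which the IGH clones they share (below) leave in doubt. Without titled control 1, 2, 3 or 4, 5 of the 7 calls were left, IgG2b and IgE being lost (permutation adjusted p = 0.0653). The sets still did not overlap for these 2 isotypes. IgA, the mucosal class, was level at 13.7% ± 1.26 and 13.6% ± 1.34 (exact permutation p = 0.943). The files name the IgG2a/c class IGHG2C, although BALB/c mice carry the Ighg2a gene at this locus.

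**Figure D4:**
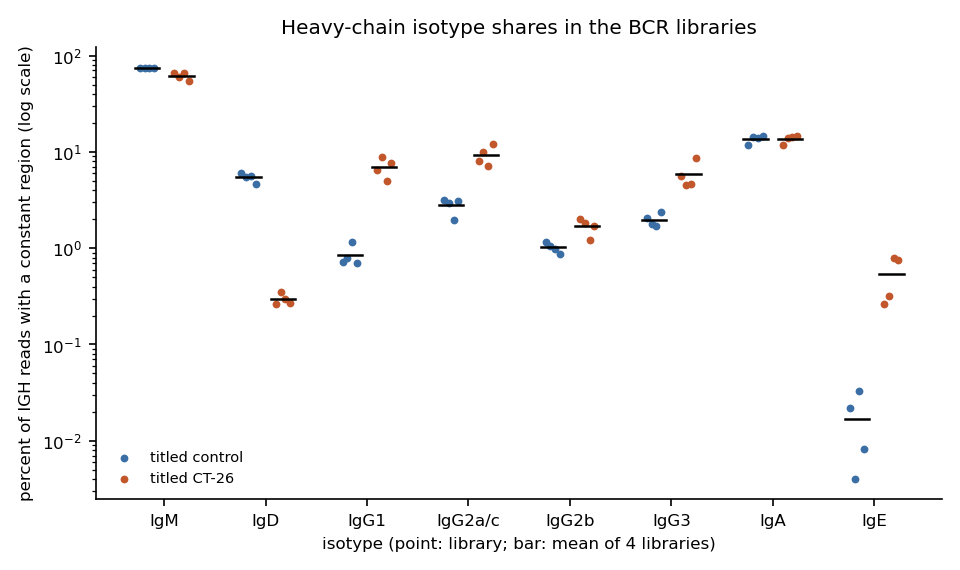
Percent of IGH reads with a constant region that belong to each isotype (vertical log axis), for the 4 BCR libraries of each set. Points are libraries and bars are means; IgD lies at 5.44% and 0.294%, IgE at 0.0167% and 0.536%, and IgA at 13.7% and 13.6% in the titled control and titled CT-26 sets.

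The RNA libraries of the same titles gave levels of the constant genes without receptor amplification, set out here as values with no test across assays. CPM are taken over all transcripts and isotype shares over IGH reads alone, so a level and a share need not move alike. Ighd fell from 442 ± 96.9 to 28.6 ± 6.78 CPM, and Ighg1 rose from 19.7 ± 10.9 to 172 ± 53.1 CPM, the same directions as the IgD and IgG1 shares. Others differed from their shares: Igha had a log2 fold change of -0.82 (edgeR adjusted p = 0.00890) beside a level IgA share, and Ighg2b did not pass (0.34, edgeR adjusted p = 0.433) beside a higher IgG2b share. Ighm did not pass (log2 fold change 0.08) beside a lower IgM share, and the lambda constant gene Iglc3 fell from 794 ± 135 to 237 ± 60.8 CPM. The T cell receptor constant genes Trac, Trbc1 and Trbc2 changed by -1.58, -2.58 and -2.33. Trbc1 and Trbc2 are near-identical copies whose counts cannot be split with certainty.

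V segment usage was compared on the number of distinct clonotypes per segment, with edgeR's quasi-likelihood test. In the heavy chain, 40 of 126 IGHV segments differed, 36 of them used less in the titled CT-26 libraries. The count fell to 25 without titled control 4, to 14 without titled CT-26 2, and to 17 without titled CT-26 3 or 4. With the titled control libraries, which share clones, taken as 1 sample that is assumed to vary like the titled CT-26 libraries, 5 IGHV and 2 IGKV segments passed in edgeR, of which 3 and 2 were also called with 4 libraries per set. The common segment IGHV4-1 rose from 12.8% ± 2.33 to 23.2% ± 2.36 of clonotypes (SD, n = 4 per set, edgeR adjusted p = 0.00601). IGHV4-1 with IGHJ4 and a 13 amino acid CDR3, the class of the largest titled CT-26 1 clone, held 3.92% there and at most 1.42% elsewhere. IGHV4-1 with IGHJ2 and 13 amino acids held 3.19% in titled CT-26 3, whose largest clone has this class, and 3.09% in titled CT-26 2, whose largest has not. Whether such clonotypes are variants of expanded clones was not tested. IGHV1S135, IGHV1S41 and IGHV1-84 had log2 fold changes of -3.00, -1.97 and -1.54. With TMM scaling, 14 IGHV segments passed, 7 higher and 7 lower. In the kappa chain, 22 of 102 IGKV segments differed, 6 higher and 16 lower, or 23 with TMM, 11 higher and 12 lower. IGKV6-23 fell from 3.01% ± 0.524 to 1.37% ± 0.272 and IGKV1-110 from 4.41% ± 0.746 to 2.51% ± 0.399, with IGKV17-121 and IGKV1-99 at -1.88 and -1.38. In the T cell chains, 6 of 64 TRAV segments differed, 3 higher and 3 lower, and 6 of 23 TRBV segments, 2 higher and 4 lower. Of the TRAV calls, 2 or 3 were left without titled control 1, 2, 3 or 4 or titled CT-26 2 or 4, and 2 with a replicate block. TRBV segments numbered 2 without titled control 1, 1 without titled control 2 or 4, and 3 without titled CT-26 1. Counted by reads, 14 TRAV segments differed, 3 higher and 11 lower. With TMM these counts became 3 TRAV segments, all higher, and 6 TRBV segments, 1 higher and 5 lower. TRAV3-3 changed by 0.73 ± 0.10 (SE), TRAV12-3 rose from 5.57% ± 0.307 to 8.32% ± 1.17, and TRAV3-1 and TRAV8-2 changed by 0.61 and -0.56. TRBV19 rose by a log2 fold change of 0.57, TRBV5 fell from 8.58% ± 0.353 to 5.23% ± 1.49, and TRBV31 and TRBV13-1 changed by 0.54 and -0.30. Without titled control 1, 2 or 4 the TRBV5 and TRBV13-1 calls were lost, and without titled control 2 or 4 that of TRBV31; TRBV13-1 was also lost without titled CT-26 1 or 3. Those of TRAV3-1 and TRAV8-2 were lost without titled control 1, 2 or 3 or titled CT-26 2 or 4, and TRAV8-2 also without titled control 4.

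Invariant T cells carry a fixed alpha chain. The rearrangement of invariant natural killer T cells (TRAV11 with TRAJ18) took 0.374% ± 0.139 of TRA reads in the titled control libraries and 0.101% ± 0.0282 in the titled CT-26 libraries (SD, n = 4 per set; exact permutation p = 0.0286), with all 4 libraries of one set above the other, but missed the threshold after adjustment for 2 tests (adjusted p = 0.0571). As a share of distinct TRA clonotypes it went the other way, 0.160% ± 0.0959 and 0.215% ± 0.0783 (exact permutation p = 0.486). That of mucosal-associated invariant T cells (TRAV1 with TRAJ33) did not differ beyond the spread, at 0.0167% ± 0.00927 and 0.0232% ± 0.0317 (exact permutation p = 0.800). It had 0 reads in titled CT-26 1 and titled CT-26 2, which allow shares of up to 0.00663% and 0.0180%. Mean CDR3 length over clonotypes was shorter in the titled CT-26 libraries for 3 chains. The lengths were 13.97 and 13.89 amino acids for TRB, 10.92 and 10.88 for IGK, and 11.10 and 11.04 for IGL. Each had an exact permutation p of 0.0286 and an adjusted p of 0.0476. Without titled control 1, 2, 3 or 4, 0 of these 3 calls were left, although the sets still did not overlap. TRA (15.55 and 15.55) and IGH (13.52 and 13.66) did not pass.

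The last comparison asked whether libraries of one set share clones more than libraries of different sets. The titled control BCR libraries shared most of their abundant heavy-chain clones, and the titled CT-26 libraries shared fewer. Of IGH sequences with at least 100 reads, a second library of the same set held between 97.7% and 100% in the titled control set and between 7.89% and 35.9% in the titled CT-26 set. The mean Morisita-Horn overlap of IGH CDR3 sequences, which is 1 for identical repertoires, was 0.947 among titled control libraries, 0.0301 among titled CT-26 libraries and 0.0306 across the sets (exact permutation p = 0.0286 over 35 splits). For TRB it was 0.0756, 0.00480 and 0.0119 (exact permutation p = 0.0286). Each p pools both sets. By these values the titled CT-26 libraries overlapped no more with each other than across the sets. Neither the IGH nor the TRB call held without titled control 1, 2, 3 or 4. Matched by V, J and CDR3 nucleotides, the values were 0.837, 0.0194 and 0.0128 for IGH and 0.0432, 0.00101 and 0.00465 for TRB. By this match the IGH mean among titled CT-26 libraries lay above that across the sets. The call for the number of shared TRB sequences was lost (exact permutation p = 0.457). Without the clonotypes common to titled control 3 and titled CT-26 4, the TRB values at lower depth were 0.0290, 0.00393 and 0.00560. Of the 261 IGH sequences with at least 100 reads in a titled control library, 96.9% were present in all 4 of them, against 3.74% of 1151 such sequences in the titled CT-26 set. Of TRB sequences with at least 20 reads, 4.93% of 1440 were in all 4 titled control libraries and 0.0854% of 1171 in all 4 titled CT-26 libraries. The labels do not say that the 4 libraries of a set came from separate animals, for receptors or for RNA. An exact p for a receptor result, like an edgeR p, measures the spread between libraries only. Clonotypes present in at least 6 of the 8 libraries numbered 29 for TRA, 7 for TRB, 274 for IGH, 8047 for IGK and 1829 for IGL. Titled control 3 and titled CT-26 4 shared 1868 TRB sequences, whereas the other pairs across the sets shared between 28 and 138.

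**Figure D5:**
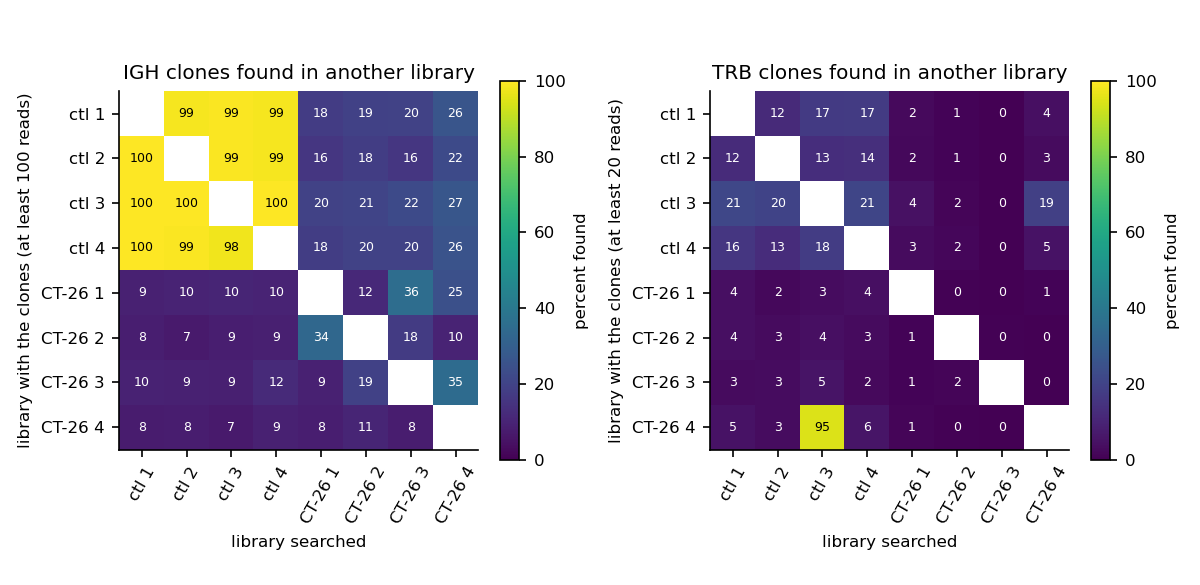
Percent of the abundant clones of 1 library (vertical axis) found in another library (horizontal axis), for IGH sequences with at least 100 reads (left) and TRB sequences with at least 20 reads (right). Each square is 1 ordered pair of the 8 libraries; IGH values among titled control libraries lie between 97.7% and 100%, and 94.7% of the abundant TRB sequences of titled CT-26 4 were found in titled control 3.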

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

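The rule for values far from the other 3 libraries of a set (Dixon's ratio) was planned, but its use on Klf9 and on the IGH to light chain ratio was chosen only after their values were seen. It was applied to 368 groups of 4, where chance gives about 1 in 20, or 18, and 23 values were found.

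Pancreas transcripts stood out in 1 RNA library of each set: 0.127% of counts in titled control 4 (others at most 0.0234%) and 0.0817% in titled CT-26 3 (others at most 0.00659%). In these libraries the pancreatic enzyme genes Cpa1 (363 and 148 CPM) and Ctrb1 (488 and 578 CPM) were high, as was Cela1 in titled control 4 (58.9 CPM).

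Among other genes, Per1 was at 4.30 CPM in titled control 3, Ms4a4c at 1.14 in titled CT-26 4, Clec2d at 28.8 in titled control 1, Gzma at 66.8 in titled control 4, Klf9 at 3.62 in titled control 2 and Dusp1 at 31.3 in titled CT-26 3. In titled CT-26 1, Ncr1 was at 5.31 CPM, Ly6d at 14.2 and Psmb9 at 15.9.

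Among receptor values, titled control 3 had an IGH to light chain read ratio of 0.234 and 61700 IGH clonotypes at equal depth. TRA clonality was 0.0581 in titled CT-26 1, IGL clonality 0.564 in titled control 4, and mean IGH CDR3 length 14.16 amino acids in titled CT-26 3. TRBV19 made 19.9% of TRB clonotypes in titled CT-26 2, and IGKV1-110 made 3.11% of IGK clonotypes in titled CT-26 1.

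Delta chain (TRD) reads, which no comparison used, took 0.638% ± 0.305 of TCR reads in the titled CT-26 libraries and 0.311% ± 0.0217 in the titled control libraries (SD, n = 4 per set), with 1.07% in titled CT-26 4. Their number was lower, 214 to 429 against 491 to 667 reads, and the delta constant gene Trdc had 7, 8, 8 and 7 counts against 31, 66, 28 and 41 in the RNA libraries.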

How the results depend on the processing

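Scaling by library totals, leaving out mitochondrial genes or the libraries with most pancreas counts, taking the titled control libraries as 1 sample, and leaving out the TCR clonotypes or libraries of the sharing pair were chosen only after seeing the data; the other alternatives were planned. The cause of each change was not tested unless stated.

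Of 2740 genes, 1698 passed a minimum fold of 1.5, and leaving out a library gave 2517 to 2948 genes and 12 to 14 lists. Of the 18 lists tested, camera called 12, camera with an estimated correlation 0 (5 at an unadjusted p under 0.05) and fry 14. Of 121 genes named by the rule, none that passed in the main fit changed sign in any setting. A change of sign in a gene that had not passed was counted as a kept call. Of 2049 planned values 1960 kept their call, 73 lost it and 16 gained one. Named V segments lost 28 of 192 planned and 17 of 32 added calls. Of 432 other planned values 350 held, 47 lost and 2 gained a call, 32 moved and 1 reversed.

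Without clonotypes of 1 read, the IGK number changed by -3526 and its clonality by 0.00499, and IGL by -20.8 (a reversed sign) and -0.0119. At a 10-fold lower depth the IGK number changed by -188. With the titled control libraries as 1 sample the smallest p is 0.200, so no call can be made: TRA changed by -6083 and 0.0755 (number and clonality), TRB by -6592 and 0.0890, IGH by -17510 and 0.0573, IGK clonality by 0.0163 and IGL by 870 and -0.0111, and isotypes and CDR3 length had 0 calls each. Overlap needs pairs and has no value there. TRAV and TRBV then had 0 segments (3 and 5 at an unadjusted edgeR p under 0.05), IGHV 5 and IGKV 2, the lone sample being assumed to vary like the titled CT-26 libraries.

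TRAV segments numbered 14 by reads, 2 with a replicate block, 3 with no minimum, 3 with TMM, 3 without the TCR clonotypes in both titled control 3 and titled CT-26 4, and 2 without both libraries. TRBV had 3 by reads and IGHV 14 with TMM.

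Leaving out 1 library gave 0.0706 to 0.0880 for TRA clonality and -0.0129 to -0.00966 for IGL clonality. CDR3 length then had 0 to 3 calls and overlap 0 to 4. All 4 results lost their calls without titled control 1, 2, 3 or 4. For both clonalities and the 3 called CDR3 lengths, the sets still did not overlap. TRAV ranged from 2 to 8 (over 1.5-fold fewer without titled control 1, 2, 3 or 4, or titled CT-26 2 or 4), TRBV from 1 to 9 (over 1.5-fold fewer without titled control 1, 2 or 4, or titled CT-26 1) and IGHV from 14 to 40 (over 1.5-fold fewer without titled control 4, or titled CT-26 2, 3 or 4).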

Other observations

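All tests of explanations in this part were chosen only after the results were seen. The direction of the title groups, tumour or healthy, was not tested, because the labels conflict.

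Abundant IGH clones of the titled control libraries were nearly all present in all 4 of them. Low-level crossover of reads would leave a clone far rarer in the second library than in the first. The median ratio of the second highest share to the highest was 0.741. For clones shared among titled CT-26 libraries this median was 0.0256, so for that set the ratio does not speak against crossover. Independent formation of the same rearrangement would spare clones with a CDR3 of at least 15 amino acids, yet 96.9% of these 64 were in all 4 libraries. A shared source of B cells or RNA for the 4 libraries stays open, since the share of clones in all 4 (96.9% of 261, against 3.74% in the titled CT-26 set) is the pattern itself and no value here tests it. At 20 reads or more, 66.7% of 1856 IGH clones and 4.93% of 1440 TRB clones were in all 4.

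Titled control 3 and titled CT-26 4 shared 1868 TRB sequences, against at most 138 in the other pairs across the sets, which speaks against public clonotypes. Material of titled CT-26 4 in the titled control 3 library is a candidate explanation: 94.7% of the 207 abundant TRB sequences of titled CT-26 4 were in titled control 3. The largest clonotype of titled CT-26 4 goes the other way, with 113 reads there and 0 in titled control 3. In the reverse direction 18.8% of 394 were found, but the depths differed. Titled control 3 had 153300 productive TRB reads and titled CT-26 4 had 14939. The shared sequences held 75.4% of the reads of titled CT-26 4 and 8.51% of those of titled control 3.

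The RNA lists moved in opposite directions. A lower share of B and T cells alone would raise the red pulp macrophage list like the granule list. The macrophage median was -1.70 instead (quartiles -1.98 to -0.49, against 2.89 to 4.16 for the granule list). Scaling moves all genes of a library alike, so the lists would overlap. The lower quartile of the granule list lay 4.65 above the upper quartile of the B cell list. These macrophage, granule and B cell values are part of the pattern itself, so they are no separate test of either explanation. More erythroid and neutrophil-lineage cells diluting all other types alike would give quartiles that overlap those of the B cell list, found for 4 of 5 other lists, the monocyte list (-1.46 to -0.35) lying above the B cell list (-3.27 to -1.75). Unequal changes in several cell types remain open and could not be weighed without cell counts.

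Other splits of the 8 libraries into sets of 4 were run with the same tests. Of 35 splits, 1, the title split, gave as many genes (2740, highest other 0). Each other split mixes the title sets, so any difference between them widens the spread within its sides and lowers its count. The low gene and V segment counts of other splits therefore cannot exclude chance. For lists, 6 of 35 splits gave at least the 12 of the title split, up to 13, so the number of lists alone does not exclude chance. The other 5 were among the 16 splits that keep 3 of 4 titles together (8 to 13 lists), while the 18 splits balanced for title gave 0 to 7. TRAV, TRBV, IGHV and IGKV segments each had 1 of 35 splits, with 6, 6, 40 and 22 calls against at most 0, 1, 1 and 1 in other splits. These splits take the 8 libraries as separate samples, which the labels do not state. The shared IGH clones of the titled control libraries leave it in doubt for IGHV and IGKV.

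The following values were chosen after they were seen. Per1 had 0, 0, 4 and 0 counts in the titled control libraries and 105, 96, 73 and 57 in the titled CT-26 libraries, while Clock, a partner in the circadian clock, had 26, 23, 27 and 27 counts and then 7, 8, 8 and 11, and Nr1d2 had a log2 fold change of -0.02. The glucocorticoid targets Fkbp5, Klf9 and Ddit4 changed by 1.87, 2.61 and 1.27, Sgk1 by -1.07, and Tsc22d3 had 68, 109, 43 and 53 counts and then 238, 134, 216 and 128. The TRA to TRB read ratio was 0.537 ± 0.0512 and 1.32 ± 0.202 (SD, n = 4 per set), and the IGH to light chain ratio 0.303 ± 0.0467 and 0.615 ± 0.0480. TRG took 0.0870% ± 0.0152 and 0.0278% ± 0.0105 of TCR reads. In titled CT-26 3, IGHV5-17 with IGHJ4 and a CDR3 of 22 amino acids had 2284 clonotypes, 5.17% of its IGH reads, against at most 38 in any other library.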
